A study of Mus musculus with 12 samples.

How the data were processed

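Total RNA of CGR8 mouse embryonic stem cells was sequenced as 12 libraries, 3 in each of 4 groups, after column purification and standard Illumina library preparation, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The deposited raw table holds estimated counts for 52661 Ensembl genes, which need not be whole numbers. Of all values in a library, zeros included, 53.8% to 58.3% were not whole. Since 28335 to 30677 genes in a library were above 0, nearly all values above 0 were not whole. The most common low value above 0 was 1.09 to 1.18 counts in the libraries numbered 1 and 2 and 0.498 to 0.531 counts in those numbered 3. The deposited normalized table is on a log2-like scale with 1 floor for all zero counts, and for the 64 genes over 20000 counts in all libraries it is a constant multiple of the raw value within each library; it was not used in any test. The authors' deposited table of comparisons has 20347 genes and gives, per the file headers, a log2 fold change, a signed fold change (a score without values between -1 and 1), a p-value and an adjusted p-value for each of the 6 pairs of groups. Its adjusted p-values equal Benjamini-Hochberg values of its p-values to within 2.79e-07, and its model is not given in the sources used here. FastQC 0.11.5, STAR 2.5.2b, Bowtie, Bowtie2, R 3.3.2 and DESeq2 are named in the submitters' processing notes, with the builds mm10, GRCm38.p5 and GRCh38, without the role of each. Which program estimated the counts, and whether strand was used, is not given in the sources used here, so reads of near-identical or overlapping genes may have been divided between them.

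The design had assumed whole-number counts. The estimated counts were therefore rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1; package data.table, version 1.17.8). Of the 52661 IDs, 52566 matched the GENCODE M21 annotation (GRCm38), which gave names and coordinates. All 12 libraries entered 1 fit with the group as the only term, with TMM normalization and the filterByExpr filter, which kept 21053 genes. Each of the 6 comparisons was a contrast tested with the edgeR quasi-likelihood F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. CPM values use the TMM library sizes, and the SD is over n = 3 libraries. An exact permutation test of 3 against 3 libraries could not go below 0.1, so none is given.

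The replicate numbers are shared by the groups. Libraries with the same number deviated together from their group means, with correlations of 0.58 to 0.88 over all pairs, above the minimum of 0.1 set for treating the numbers as pairs; 11 of the 12 libraries correlated best with their own number. Between numbers 1 and 2 the correlations were 0.49 to 0.76, and between number 3 and another number the highest was -0.60. The minimum was thus also met across numbers 1 and 2, so it sets only number 3 apart. The pairing is read from the titles and from these correlations, and the labels do not say what a number stands for. The paired fit adds the replicate number as a block to the same model. Within-number values are differences between the libraries of the 2 groups with that number; a number has 1 library per group, so they have no test.

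Gene lists were tested with camera on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and again with an estimated correlation, in both directions, adjusted over the lists of a comparison. The 24 lists cover pluripotency (naive, core, formative and primed), the 2-cell-like state, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm, targets of Wnt, ERK, LIF, BMP, Nodal and p53, netrin receptors, integrins, the unfolded protein response, cholesterol biosynthesis, hypoxia, germ-cell genes silenced by DNA methylation, imprinted genes, fibroblast markers, Y-linked genes and mitochondrially encoded mRNAs. Ddit3 and Aldoa have 2 Ensembl IDs each and count as 2 members of their lists. The fit without pairing, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule took the genes with the largest absolute log2 fold change that passed the threshold, had a mean of at least 5 CPM in the higher group, a conventional symbol and all 3 libraries of 1 group above the other: 10 each way for netrin-1 WT against control, 8 each way for a mutant against netrin-1 WT and 5 each way for the other comparisons. It added a set of receptor and pluripotency genes and up to 4 members of each list with at least 1 CPM. The same rule on the paired fit, with within-number differences of 1 sign in place of separated groups, the naming of Magee2, and the chromosome parts and chromosome 9 neighbours were chosen after the data were seen.

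Other settings were RLE size factors, no filter beyond 1 count (39352 genes), at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the 2 groups compared, a threshold of 0.01 and each library left out in turn. Settings added later were the same ones in the paired fit, numbers 1 and 2 alone, number 3 as a covariate and counts without genes of 3 chromosome parts. The overlap of comparisons against the shared control was set beside 10 simulations of unchanged groups. The fits were tested on simulated data drawn from the control means and the dispersions of the paired fit at the real library sizes. Known changes were put into the netrin-1 WT group. Neighbouring genes were scanned in windows of 15 genes with over 10 CPM against 1000 permutations of the gene order. Figures were drawn with matplotlib 3.10.9. The values of 1 member of the primitive endoderm list are not reported here, and it stays in the counts and tests of the list. Summed counts were 22256195 to 24736421 in the number 3 libraries and 32370919 to 59735737 in the others. The replicates of a group differed by more than sampling noise (chi-square per degree of freedom 20.0 to 523), so none was counted as a duplicate. Floors of 3 counts over a group cover counting error only.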

Results

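RNA-seq gene counts were available for 12 libraries of CGR8 cells, a mouse embryonic stem cell line, grown with serum and leukemia inhibitory factor (LIF), a cytokine that keeps these cells pluripotent. The cells had been stably transfected with an empty expression vector (control, n = 3) or with the same vector encoding netrin-1, a secreted laminin-related guidance protein whose receptors include Dcc, neogenin (Neo1) and the Unc5 family. Netrin-1 was wild type (netrin-1 WT, n = 3) or a point mutant named for its receptor Unc5b (unc5B MUT, n = 3) or for neogenin (neo1 MUT, n = 3). The design asks how the transcriptome differs between cells with and without netrin-1, and between cells with the wild-type protein and with a protein altered in its interaction with 1 receptor. Summed estimated counts ranged from 22256195 to 59735737 per library. CPM values are group means ± SD over n = 3 libraries. The labels do not say that the 3 libraries of a group came from separate cultures. P-values therefore measure the spread between these libraries, which may be technical. In a fit with the replicate number as a block, they measure only the spread left after the number is taken out.

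The replicate number had a larger effect on the libraries than the group. The first principal component of log2 CPM held 70.2% of the variance and set the 4 number 3 libraries apart from the other 8, and 12005 genes differed between the number 3 and number 1 libraries at an adjusted p of 0.05 (edgeR quasi-likelihood test). Between the number 2 and number 1 libraries 0 genes differed. The number 3 libraries held 22256195 to 24736421 counts, and processed pseudogenes took 3.92% to 4.28% of them, against 2.08% to 2.41% in the other libraries. Libraries with the same number deviated together from their group means (correlations of 0.58 to 0.88), so each count of changed genes is given from the fit without the replicate number and from the paired fit, which has the number as a block. Fold changes ± SE and adjusted p-values of genes and gene lists are from the paired fit unless the unpaired fit is named, and "rose" and "fell" are used of genes that passed its threshold. Simulated data were drawn from the control means and dispersions of the paired fit (20167 genes), with known changes put into netrin-1 WT. In them the unpaired fit recovered 11.6% of the genes changed 4-fold and 0% of those changed 2-fold, and the paired fit recovered 62.1% and 33.8%. The simulated data hold the replicate effect that the paired fit assumes, so its advantage there is partly built in. Over 3 such simulations the paired fit called 22 unchanged genes beside 195 recovered ones, and the unpaired fit 0 beside 23. An unchanged list passed an unadjusted camera test in 1 of the 3 with the block and in 0 without it.

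**Figure D1:**
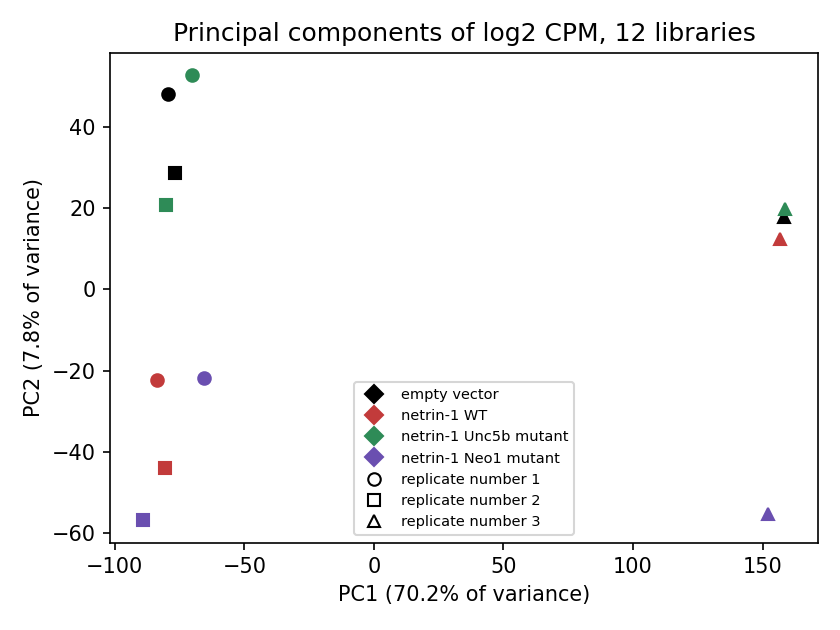
Principal components of log2 CPM for the 12 libraries, with the first component (70.2% of the variance) on the x axis and the second (7.8%) on the y axis, both in arbitrary units of log2 CPM. Points are single libraries marked by group and replicate number, and the 4 number 3 libraries lie between 152 and 159 on the first component while the other 8 lie between -89.3 and -65.6.

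The Ntn1 transcript (ENSMUSG00000020902, chromosome 11, 68209364 to 68400823, minus strand, GRCm38) was higher in each of the 3 netrin-1 groups than in control in all 3 numbers. Ntn1 was at 8.43 ± 7.34 CPM in control, 196 ± 108 CPM in netrin-1 WT, 187 ± 144 CPM in unc5B MUT and 159 ± 89.2 CPM in neo1 MUT. These are counts of the mouse gene, from its own transcript and any matching transcript of the vector, which the values do not separate; the labels do not give the species or extent of the netrin-1 sequence in the vector. The SDs are wide because every number 3 library was lower: control libraries 1, 2 and 3 held 15.4, 9.09 and 0.78 CPM, and netrin-1 WT libraries 288, 223 and 76.9 CPM. The log2 fold changes against control were 4.85 ± 0.36, 4.48 ± 0.35 and 4.52 ± 0.36 for netrin-1 WT, unc5B MUT and neo1 MUT (edgeR adjusted p = 0.000293, 0.0016 and 0.000169); without pairing the adjusted p-values were 0.271, 1 and 0.255. Between netrin-1 WT and the mutants the Ntn1 difference did not pass the test: the log2 fold change was -0.37 ± 0.30 for unc5B MUT (adjusted p = 0.562; 0.16, -0.12 and -1.14 in numbers 1, 2 and 3, and -0.066 without pairing) and -0.34 ± 0.30 for neo1 MUT (adjusted p = 0.671). The receptors Neo1 and Unc5b were measured in every group, at 62.9 ± 21.5 and 24.3 ± 1.23 CPM in control, and neither passed the test in any of the 6 comparisons. Dcc did not pass the filter on low counts; its highest value was 1.26 CPM, in netrin-1 WT library 1.

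**Figure D2:**
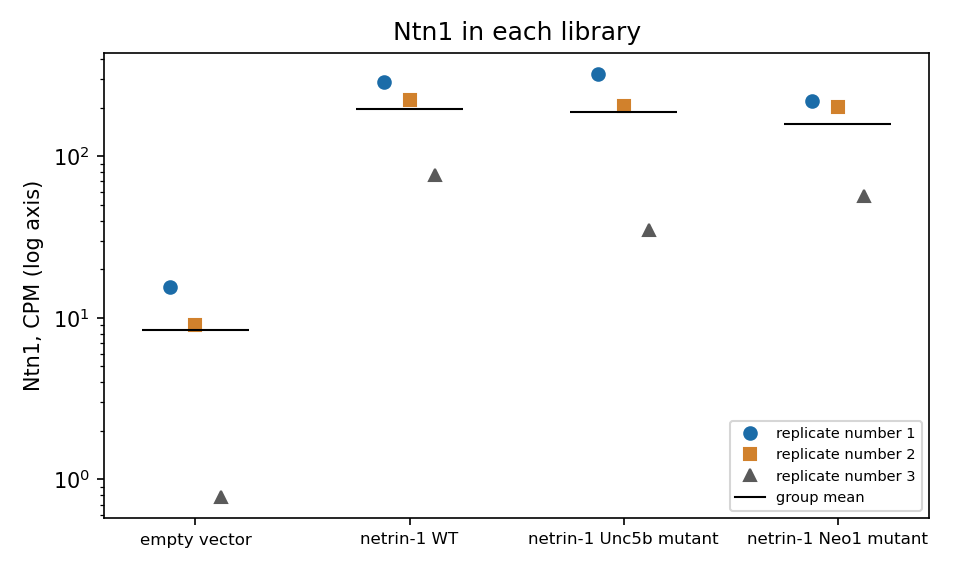
Ntn1 level in CPM (y axis, log scale) for each of the 12 libraries by group (x axis), with markers for the replicate number and a line at the group mean. Every netrin-1 library exceeds the control library of the same number, and the number 3 library is the lowest in each of the 4 groups.

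Netrin-1 WT against control sets the cells with wild-type netrin-1 against those with the empty vector. Markers of primitive endoderm, the extraembryonic lineage that appears next to the pluripotent epiblast, were the group with the largest decrease. Of 18 tested members 16 fell (17 when adjusted over the list alone), with a median log2 fold change of -2.43 (-2.84, -2.52 and -2.12 in numbers 1, 2 and 3). Among them were the transcription factors Gata6 (62.8 ± 14.3 CPM in control, 13.3 ± 3.33 CPM in netrin-1 WT) and Sox17 (13.3 ± 4.93 and 1.29 ± 0.43 CPM), the adaptor Dab2 (103 ± 9.96 and 7.11 ± 2.28 CPM) and the endocytic receptor Cubn (125 ± 22.4 and 9.01 ± 3.69 CPM). Members of the 2-cell-like list, which holds the Zscan4 family and other genes that mark a rare state resembling the early embryo, rose in 6 of 14 cases (10 when adjusted over the list alone), with a median of 2.29. The stress-response genes of the unfolded protein list fell in 3 of 15 cases, where Ddit3 counts as 2 because it has 2 Ensembl IDs (7 fell when adjusted over the list alone), with a median of -0.87. Among pluripotency factors Sox2 rose (log2 fold change 0.75 ± 0.14, adjusted p = 0.0144), while Pou5f1 (-0.17 ± 0.09, adjusted p = 0.339), Nanog (0.74 ± 0.30, adjusted p = 0.215) and Esrrb (0.33 ± 0.16, adjusted p = 0.316) did not pass. Of the 11 core pluripotency genes 1 rose (1 rose and 2 fell when adjusted over the list alone).

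The unpaired fit called 21 of 21053 genes (7 higher, 14 lower) and the paired fit 737 (367 higher, 370 lower), among them the 21; 440 of the 737 changed at least 2-fold. The primitive endoderm list had adjusted p = 8.98e-26 in the camera test and adjusted p = 0.0874 with an estimated correlation; in the unpaired fit 6 members were called and the adjusted p was 0.00424 with an estimated correlation. Among the 6 were Dab2, Sox17, Amn, Gata6 and Pdgfra. Amn (ENSMUSG00000021278, chromosome 12, 111271095 to 111276426), the partner of Cubn, fell from 17.3 ± 1.17 to 2.15 ± 0.16 CPM (log2 fold change -2.99 ± 0.19, adjusted p = 0.000159). Other genes with the largest decreases under the naming rule were Habp2, Aqp8, Nxf7, Hkdc1, Nostrin, Clic6, Tcf23 and Dkk1, with log2 fold changes between -4.89 and -3.64. Dkk1, a secreted Wnt antagonist, fell from 8.15 ± 3.76 to 0.57 ± 0.33 CPM. Nxf7 on the X chromosome fell from 12.4 ± 4.03 to 0.65 ± 0.06 CPM. Srgn, Myo7a and Lgals9 fell by 3.37, 3.17 and 2.59 on the log2 scale.

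Several of the genes that rose lay close together. Chromosome 3 from 5 to 55 Mb held 235 of the tested genes (1.12%) and 86 of the 367 that rose (23.4%), among them Supt20, Alg5 and the transcription factor Sox2. The median log2 fold change of its 96 genes with over 10 CPM was 0.92, and it was 0.98, 0.96 and 0.79 in numbers 1, 2 and 3. Within it Setd7, Supt20 and Cog6 rose by 1.58, 1.49 and 1.49 on the log2 scale. Just past it, Sohlh2 (ENSMUSG00000027794, chromosome 3, 55182028 to 55209957) rose from 64.0 ± 6.23 to 271 ± 33.8 CPM. Sox2 rose from 322 ± 76.2 to 557 ± 218 CPM; the call was lost without control library 1 or 2 or netrin-1 WT library 1 or 2 (adjusted p = 0.0747, 0.0835, 0.0712 and 0.0786). On chromosome 6 from 120 to 137 Mb, 27 of 188 tested genes rose, with a median of 0.42 over 78 genes; this part holds Dppa3, a naive pluripotency gene (2.24 ± 0.36), the glucose transporter Slc2a3 (0.87 ± 0.18) and Nanog, which did not pass. Chromosome 15, which holds Dab2, Itga5 and Sqle, had 59 of the 370 genes that fell (15.9%, against 3.82% of the tested genes) and a median of -0.34, which was -0.49 and -0.46 in numbers 1 and 2 and -0.06 in number 3. Outside these parts Lmo7, St8sia1 and Sox21 rose, Sox21 from 2.05 ± 1.43 to 25.3 ± 22.2 CPM.

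The 2-cell-like list had a camera adjusted p of 3.83e-07 and adjusted p = 0.645 with an estimated correlation. Zscan4e rose by 2.68 ± 0.35 and Zscan4d by 2.58 ± 0.40 on the log2 scale; these genes are near-identical copies on chromosome 7, so how reads were divided between them is uncertain. The unfolded protein list passed (adjusted p = 0.000296) and did not with an estimated correlation (adjusted p = 0.645); Chac1, Herpud1 and Psat1 were the members that fell. The naive pluripotency list had 2 members that rose (4 when adjusted over the list alone), Dppa3 and Tcl1, a median of 0.28 and adjusted p = 0.0251, or adjusted p = 0.645 with an estimated correlation; its median was 0.02, 0.16 and 0.73 in numbers 1, 2 and 3. The mitochondrially encoded mRNAs had 0 members called (5 lower when adjusted over the list alone), a median of -0.26 and adjusted p = 0.0022, or adjusted p = 0.645 with an estimated correlation. The Nodal target list passed in the paired fit only (median -0.82, adjusted p = 0.0273, or adjusted p = 0.645 with an estimated correlation; unpaired adjusted p = 0.168), with Lefty1 falling by 1.42 on the log2 scale. Leaving out any control library, or netrin-1 WT library 1 or 2, left 1 gene in the unpaired fit, and leaving out netrin-1 WT library 3 left 6. In the paired fit it gave 211 and 243 without control library 1 or 2, 270 and 219 without netrin-1 WT library 1 or 2, and 1861 without netrin-1 WT library 3. Of the 54 named genes called in the paired fit, 32 were called whichever 1 of the 6 libraries was left out. The Nodal list lost its call without control library 2 and netrin-1 WT libraries 2 and 3 (adjusted p = 0.127, 0.167 and 0.0606), the naive pluripotency list without control library 3 and netrin-1 WT library 3 (0.401 and 0.461) and the mitochondrially encoded mRNAs without control library 3 (0.0617).

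**Figure D3:**
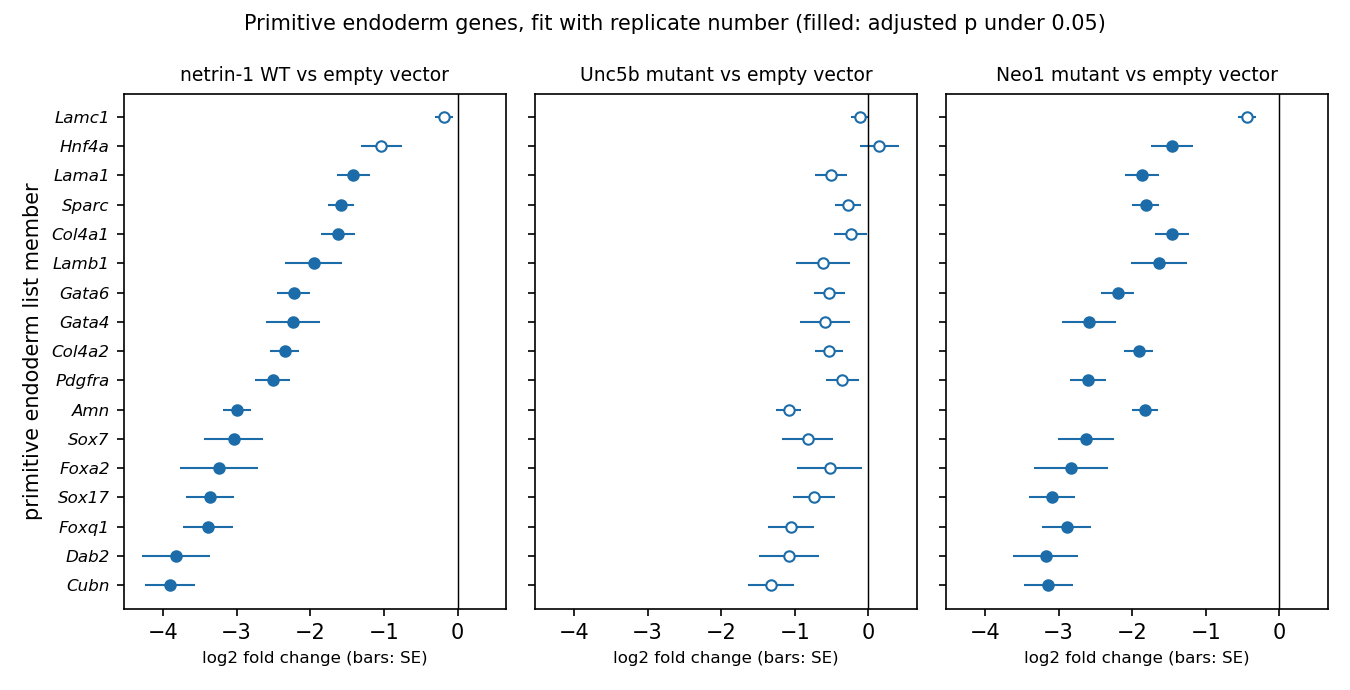
Log2 fold change (x axis, bars are SE) from the paired fit for 17 of the 18 tested primitive endoderm genes (y axis) in netrin-1 WT, unc5B MUT and neo1 MUT against control, with filled points for an adjusted p under 0.05. In netrin-1 WT the filled points lie between -3.90 (Cubn) and -1.42 (Lama1), and in unc5B MUT the open points lie between -1.32 (Cubn) and 0.15 (Hnf4a).

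Unc5B MUT against control sets the cells with the mutant named for Unc5b against those with the empty vector. Few genes differed: the unpaired fit of edgeR called 0 genes (238 at an unadjusted p under 0.05; DESeq2 called 11 and limma-voom 0), and the paired fit called 6, with 5 higher and 1 lower. The 5 that rose were Ntn1, the neighbouring chromosome 9 genes Dag1, Amt and Rhoa, and Magee2, an X-linked gene outside the rule for named genes that was chosen after its values were seen. Magee2 (ENSMUSG00000031224, chromosome X, 104854952 to 104857267) had 0 counts in all 3 control libraries and was at 2.44 ± 0.985 CPM in unc5B MUT, at least 85.2-fold higher than a floor of 3 counts over the control libraries (0.0286 CPM). In netrin-1 WT and neo1 MUT, where the unpaired fit called it too, it was at 2.84 ± 1.36 and 1.87 ± 0.736 CPM. Dag1, the laminin receptor dystroglycan, rose from 121 ± 26.6 to 255 ± 22.6 CPM (log2 fold change 1.1 ± 0.11, adjusted p = 0.00547), Amt from 23 ± 2.96 to 48.7 ± 1.76 CPM and the small GTPase Rhoa from 173 ± 48.3 to 313 ± 46.5 CPM. Strada, a pseudokinase that activates the kinase LKB1, fell from 28.7 ± 0.26 to 15 ± 0.99 CPM (log2 fold change -0.94 ± 0.13, adjusted p = 0.045).

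The primitive endoderm list was lower here too, by less: the median was -0.54, 0 members were called (3 lower when adjusted over the list alone), and the camera adjusted p was 7.72e-10, or adjusted p = 0.348 with an estimated correlation. Gata6 was at 43.3 ± 6.45 CPM against 62.8 ± 14.3 CPM in control (log2 fold change -0.53 ± 0.21, adjusted p = 0.989). The trophectoderm list (median -0.34), the cholesterol biosynthesis list (-0.18, with 0.00, 0.05 and -0.49 in numbers 1, 2 and 3) and the hypoxia and glycolysis list (-0.28) passed the camera test with adjusted p = 0.00488, 0.00536 and 0.00888 and had 0 members called, also when adjusted over the list alone. With an estimated correlation they had adjusted p = 0.226, 0.613 and 0.613. The genes of chromosome 9 from Dag1 to Rhoa (108204634 to 108337934) had log2 fold changes above 0 in all 3 netrin-1 groups, but Tcta in netrin-1 WT (adjusted p = 0.238) and Nicn1 and Tcta in unc5B MUT (0.203 and 0.401) did not pass. Dag1, Nicn1, Amt, Tcta and Rhoa had log2 fold changes of 1.02, 0.94, 1.04, 0.53 and 0.81 in netrin-1 WT, 1.1, 1.17, 1.09, 0.97 and 0.87 in unc5B MUT and 0.99, 1.1, 1.43, 0.89 and 0.88 in neo1 MUT. The next gene, Gm37401 (7.29 CPM over all libraries), had -0.026, 0.21 and 0.29, and Gpx1 after it -0.24, -0.08 and -0.55. All 3 groups were set against the same control libraries. A difference of the control cells alone would give the same pattern, also for Magee2, and this was not tested. The paired fit called 2 and 3 genes without control library 1 or 2, and 3, 2 and 2 without unc5B MUT library 1, 2 or 3. Ntn1 and Magee2 were called whichever library was left out. Dag1 was lost without control library 1 and unc5B MUT libraries 2 and 3 (adjusted p = 0.0521, 0.0716 and 0.0692), and Amt, Rhoa and Strada were called only in the absence of control library 3 or with all libraries. Without control library 3 the cholesterol list had a median of 0.07 (adjusted p = 0.687) and the hypoxia list one of -0.10 (0.369), and without unc5B MUT library 1 the hypoxia list had -0.18 (0.13).

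Neo1 MUT against control sets the cells with the mutant named for neogenin against those with the empty vector. Primitive endoderm genes were again lower, with 17 of 18 tested members falling (18 when adjusted over the list alone) and a median log2 fold change of -2.29 (-2.03, -2.05 and -2.94 in numbers 1, 2 and 3). Gata6 was at 13.6 ± 3.23 CPM, Sox17 at 1.49 ± 0.65 CPM and the receptor gene Pdgfra fell from 54.9 ± 9.4 to 9.28 ± 4.13 CPM. The 6 tested members of the Y-linked list fell, Kdm5d to 1.63 CPM (from 5.08 CPM) and the other 5 to under 1 CPM: Ddx3y fell from 84.0 ± 30.5 to 0.51 ± 0.19 CPM and Eif2s3y from 80.2 ± 15 to 0.22 ± 0.16 CPM. 2-cell-like genes rose in 5 of 14 cases (8 rose and 1 fell when adjusted over the list alone), with a median of 1.95 (1.93, 2.35 and 0.42 in numbers 1, 2 and 3).

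The unpaired fit called 27 genes (3 higher, 24 lower) and the paired fit 1108 (414 higher, 694 lower), among them the 27; 629 of the 1108 changed at least 2-fold. The primitive endoderm list had adjusted p = 3.25e-23, or adjusted p = 0.0563 with an estimated correlation; in the unpaired fit 4 members were called (Sox17, Pdgfra, Gata6 and Amn) and the adjusted p was 0.00379 with an estimated correlation. All 6 tested members of the Y-linked list fell, with a fitted median of -6.38 and adjusted p = 3.57e-16, or 0.00313 with an estimated correlation. Zfy1 had 557 counts over the 3 control libraries and 1 over the 3 neo1 MUT libraries, and Usp9y 102 and 2. With these 2 genes set at a floor of 3 counts over the group (0.0288 CPM), the median of the list was -6.24. Kdm5d kept 142 of its counts, against 485 in control (log2 fold change -1.71). Uba1y, outside the list, fell from 19.3 ± 8.72 to 0.17 ± 0.17 CPM. Of the 17 tested Y chromosome genes outside the list, 8 had 3 counts or fewer over the neo1 MUT libraries, and Zfy2 (49 counts in control, 0 in neo1 MUT) and Gm21489 (92 and 1) fell as well. Others were not low: Gm47283 was at 233 and 228 CPM in control and neo1 MUT, Gm37158 at 4.27 and 3.98 CPM, and Mid1-ps1 rose from 7.20 to 25.3 CPM (adjusted p = 0.0153). Whether the reads counted for these genes came only from the Y chromosome was not tested.

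Magee2, at 0 counts in control, was at least 65.4-fold higher than the floor of 3 counts over the control libraries. Under the naming rule, which asks for at least 5 CPM in the higher group, Thsd7a had the largest increase. It encodes a membrane protein with thrombospondin repeats and was at 5.78 ± 3.2 CPM against 0.20 ± 0.28 CPM (log2 fold change 5.21 ± 0.57, adjusted p = 0.00102, unpaired adjusted p = 0.225). Cdx1, a Wnt target, rose from 1.88 ± 0.32 to 5.45 ± 1.41 CPM, the neural gene Pax6 from 5.32 ± 2.77 to 15.5 ± 6.24 CPM and Amt from 23 ± 2.96 to 61.8 ± 6.83 CPM. Zscan4e and Zscan4d rose by 2.59 and 2.35 on the log2 scale, with the same uncertainty between copies; the 2-cell-like list had adjusted p = 0.000746, or adjusted p = 0.637 with an estimated correlation. Among Wnt targets Dkk1, Ascl2 and Axin2 fell by 3.39, 2.26 and 0.85 on the log2 scale while Cdx1 rose, and the list did not pass (median -0.45, adjusted p = 0.153). The imprinted gene list fell in 3 of 20 cases (5 when adjusted over the list alone), with H19 (-2.63), Dlk1 (-1.94) and Peg3 (-1.14). The list had a median of -0.34 (-0.42, -0.43 and 0.09 in numbers 1, 2 and 3) and adjusted p = 0.0102, or adjusted p = 0.13 with an estimated correlation. H19 differed strongly between libraries of a group (87.4 ± 88.7 CPM in control). The unfolded protein list had 2 members that fell (7 when adjusted over the list alone), Atf3 and Herpud1, with a median of -0.58 and adjusted p = 0.000746, or adjusted p = 0.337 with an estimated correlation. The list of germ-cell genes silenced by DNA methylation had 1, Dazl (4 when adjusted over the list alone), with a median of -0.47 and adjusted p = 0.0139, or adjusted p = 0.637 with an estimated correlation. The fibroblast list, which stands for feeder cells, had 2, Thy1 and Vim (3 when adjusted over the list alone), with a median of -0.53 and adjusted p = 0.0321, or adjusted p = 0.213 with an estimated correlation.

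Chromosome 15 held 129 of the 694 genes that fell (18.6%) and its 400 genes with over 10 CPM had a median of -0.44, with -0.44, -0.50 and -0.43 in numbers 1, 2 and 3. Dab2, the keratin Krt8, Ndrg1, Sqle and Itga5, which all fell, lie on it. The part of chromosome 3 that rose in netrin-1 WT had a median of 0.11. Without control library 1, 2 or 3 the unpaired fit called 6, 7 and 17 genes, and without neo1 MUT library 1, 2 or 3 it called 9, 4 and 11. In the paired fit it gave 278 and 327 without control library 1 or 2, and 403, 459 and 487 without neo1 MUT library 1, 2 or 3. Of the 50 named genes called in the paired fit, 22 were called whichever library was left out. The germ-cell list lost its call without control library 1 and neo1 MUT library 3 (adjusted p = 0.0899 and 0.0559), and the fibroblast list without control library 3 and neo1 MUT library 3 (0.155 and 0.145).

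**Figure D4:**
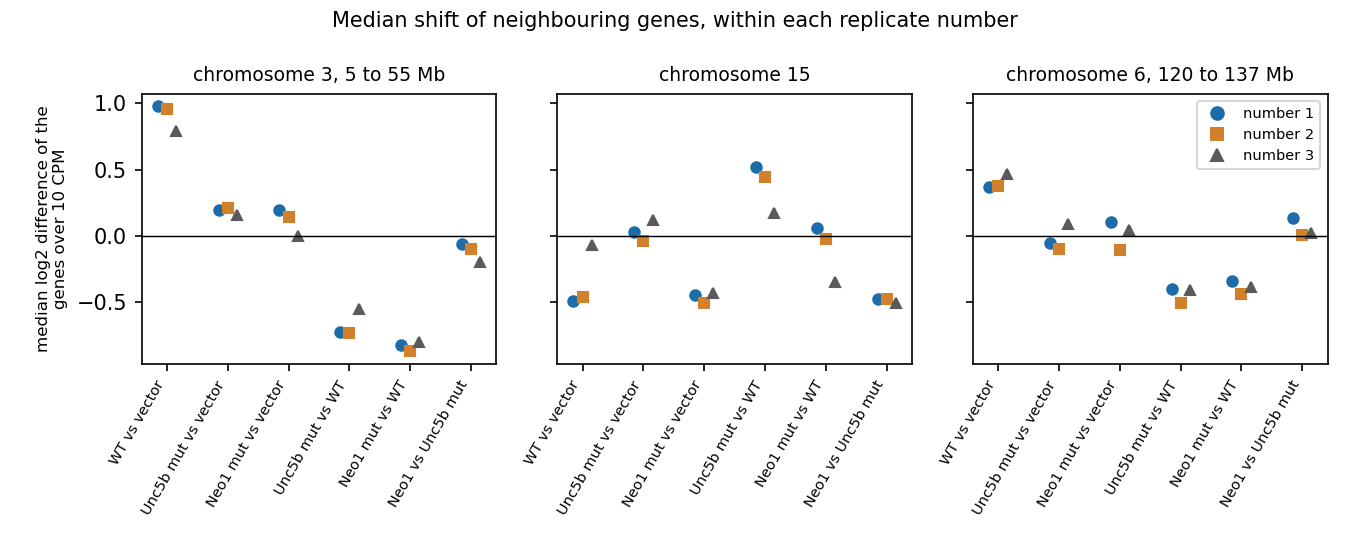
Median log2 difference of the genes with over 10 CPM (y axis) in chromosome 3 from 5 to 55 Mb, chromosome 15 and chromosome 6 from 120 to 137 Mb, for each of the 6 comparisons (x axis), with 1 point per replicate number. On chromosome 3 netrin-1 WT against control lies at 0.98, 0.96 and 0.79, and on chromosome 15 neo1 MUT against control lies at -0.44, -0.50 and -0.43.

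Genes called against the shared control overlapped. In the paired fit 115 genes rose and 221 fell in both netrin-1 WT and neo1 MUT, and 7 moved in opposite directions; independent lists of these sizes would share 7.22 and 12.2, and 10 simulations of unchanged groups against the same controls shared at most 2. The covariance of the fold changes was 0.262 against 0.0897 in the simulations, and the Pearson correlation, across genes, which are not independent replicates, was 0.553 against 0.507. For netrin-1 WT and unc5B MUT the covariance was 0.131 and 5 genes rose in both; for unc5B MUT and neo1 MUT it was 0.109 and 5 genes rose in both. The Pearson correlations of these pairs, 0.446 and 0.347, lay below the 0.507 of the simulations. In both pairs with unc5B MUT the 5 genes were those that rose there: Ntn1, Dag1, Amt, Rhoa and Magee2. The 3 control libraries are too few to be split, so part of each overlap may come from the shared controls. The unpaired fit called 6 genes in both netrin-1 WT and neo1 MUT and 0 in the other pairs, for which DESeq2 gave 6 and 5.

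Unc5B MUT against netrin-1 WT sets the cells with the mutant named for Unc5b against those with the wild-type protein. Primitive endoderm genes were higher in unc5B MUT: 14 of 18 rose (17 when adjusted over the list alone), with a median log2 fold change of 1.86 (2.09, 1.79 and 1.64 in numbers 1, 2 and 3). Gata6 was at 43.3 ± 6.45 CPM against 13.3 ± 3.33 CPM and Sox17 at 7.91 ± 2.56 CPM against 1.29 ± 0.43 CPM. Dkk1 was at 7.06 ± 3.06 CPM against 0.57 ± 0.33 CPM, and Habp2, Aqp8, Nostrin, Apobec2, Hkdc1, Tcf23 and Bmper rose by between 2.83 and 3.78 on the log2 scale. 2-cell-like genes fell in 3 of 14 cases (10 fell and 1 rose when adjusted over the list alone), with a median of -1.90.

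The unpaired fit of edgeR called 0 genes (1059 at an unadjusted p under 0.05; DESeq2 called 182 and limma-voom 0), and the paired fit called 414 (211 higher, 203 lower), of which 230 changed at least 2-fold. The primitive endoderm list had adjusted p = 4.65e-20, or adjusted p = 0.159 with an estimated correlation; in the unpaired fit the adjusted p was 0.0108 with an estimated correlation. Of the 367 genes that rose in netrin-1 WT against control, 161 fell here, and of the 370 that fell there, 161 rose here; these comparisons share the netrin-1 WT libraries, which by itself gives opposite signs. The part of chromosome 3 from 5 to 55 Mb held 63 of the 203 genes that fell (31.0%) and had a median of -0.68, which covers Lrrc31 (-2.83), Spry1 (-0.81) and the p53 target Zmat3 (-0.71). Chromosome 15 held 40 of the 211 that rose (19%), Dab2 and Sqle among them, and had a median of 0.36. On chromosome 6 from 120 to 137 Mb 22 genes fell, including Dppa3 (-2.32) and Slc2a3, which was at 533 ± 52 CPM against 1241 ± 91.1 CPM.

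The mitochondrially encoded mRNAs were higher, with 1 member called, mt-Atp6 (11 higher when adjusted over the list alone), a median of 0.45 and adjusted p = 2.62e-05, or adjusted p = 0.538 with an estimated correlation. The unfolded protein list had 2 members that rose (7 when adjusted over the list alone), Psat1 and Herpud1, with a median of 0.55 and adjusted p = 0.00125, or adjusted p = 0.538 with an estimated correlation. The 2-cell-like list had adjusted p = 5.86e-06, or adjusted p = 0.538 with an estimated correlation. The primitive streak and mesendoderm list had a median of -0.46 with 0 members called, also when adjusted over the list alone (adjusted p = 0.0227, or adjusted p = 0.302 with an estimated correlation). The Nodal target list passed in the paired fit only, with a median of 0.67 and 0 members called (2 higher when adjusted over the list alone; adjusted p = 0.0355, or adjusted p = 0.538 with an estimated correlation; unpaired adjusted p = 0.297). Without netrin-1 WT library 3 the paired fit called 1830 genes, without library 1 or 2 of that group 61 or 36, and without unc5B MUT library 1, 2 or 3 it called 36, 36 or 106. Of the 33 named genes called, 4 were called whichever library was left out, and Gata6 was lost without netrin-1 WT library 2 (adjusted p = 0.0574). The Nodal list lost its call without netrin-1 WT libraries 2 and 3 and unc5B MUT libraries 2 and 3 (0.209, 0.0733, 0.179 and 0.066), and the mesendoderm list without library 3 of either group (0.114 and 0.117).

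Neo1 MUT against netrin-1 WT sets the cells with the mutant named for neogenin against those with the wild-type protein. Of the Y-linked list 5 members were under 1 CPM in neo1 MUT and Kdm5d was at 1.63 CPM: Eif2s3y was at 0.22 ± 0.16 CPM against 55.8 ± 3.05 CPM, Ddx3y at 0.51 ± 0.19 against 62.5 ± 27.8 CPM, and all 6 tested members of the list fell. The X-linked genes Magea4 and Xlr3c fell by 3.38 and 3.37 on the log2 scale; Xlr3c and Xlr5a belong to a family of near-identical copies and are uncertain. Thsd7a rose from 0.06 ± 0.01 to 5.78 ± 3.2 CPM (log2 fold change 6.80 ± 0.66, adjusted p = 0.000822). Primitive endoderm genes were low in both groups. Of 18 members 1 rose, Amn (4.88 ± 0.35 against 2.15 ± 0.16 CPM; adjusted p = 0.0508 without neo1 MUT library 1). The list did not pass (median 0.30, and 0.70, 0.42 and -0.89 in numbers 1, 2 and 3; adjusted p = 0.476). With the libraries of numbers 1 and 2 alone, that list had a median of 0.66 and passed (adjusted p = 8.00e-05).

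The unpaired fit called 16 genes (1 higher, 15 lower), 8 of them outside chromosomes 3 (5 to 55 Mb), 15 and Y, and the paired fit 419 (83 higher, 336 lower), among them the 16; 284 of the 419 changed at least 2-fold. The Y-linked list had a median of -6.24 (-6.06 with Zfy1 and Usp9y at the floor), adjusted p = 3.20e-19 and adjusted p = 0.00181 with an estimated correlation. The part of chromosome 3 from 5 to 55 Mb held 76 of the 336 genes that fell (22.6%), with a median of -0.80; Alg5 on it fell by 1.90 on the log2 scale. On chromosome 6 from 120 to 137 Mb 15 genes fell, Dppa3 (-2.50) among them. Genes that rose included Cdx1 (1.48), Lims2 (1.76), the neuronal intermediate filament Ina (1.98) and Cass4 (2.16). The imprinted gene list had 1 member that rose, Peg10, and 3 that fell, Grb10, Peg3 and Snrpn (1 and 6 when adjusted over the list alone), with a median of -0.46 and adjusted p = 0.0356, or adjusted p = 0.267 with an estimated correlation. The naive pluripotency list had a median of -0.19 with Dppa3 called (3 lower when adjusted over the list alone; adjusted p = 0.0218, or adjusted p = 0.682 with an estimated correlation). Without netrin-1 WT library 1, 2 or 3 the unpaired fit called 8, 9 and 9 genes, and without neo1 MUT library 1, 2 or 3 it called 8, 9 and 9. In the paired fit it gave 254 and 147 without netrin-1 WT library 1 or 2, and 153, 203 and 211 without neo1 MUT library 1, 2 or 3. Of the 32 named genes called, 16 were called whichever library was left out. The imprinted list lost its call without netrin-1 WT library 1 and neo1 MUT libraries 1 and 2 (adjusted p = 0.0636, 0.0798 and 0.116), and the naive list without netrin-1 WT library 3 and neo1 MUT libraries 1 and 2 (0.119, 0.109 and 0.0806).

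Neo1 MUT against unc5B MUT sets the mutants against each other. Primitive endoderm genes were lower in neo1 MUT, with 16 of 18 falling (18 when adjusted over the list alone) and a median log2 fold change of -1.73 (-1.41, -1.38 and -2.44 in numbers 1, 2 and 3). Pdgfra was at 9.28 ± 4.13 CPM against 44.0 ± 15.2 CPM. Strada was higher, at 35.1 ± 2.31 CPM against 15 ± 0.99 CPM, as was Firre, an X-linked long non-coding RNA, at 142 ± 22.1 CPM against 46.0 ± 8.77 CPM. Serpina3m fell from 8.96 ± 5.33 to 0.43 ± 0.12 CPM. The 6 tested Y-linked genes fell, and 2-cell-like genes rose in 2 of 14 cases (7 rose and 1 fell when adjusted over the list alone), with a median of 1.54, which was 1.98 and 1.58 in numbers 1 and 2 and -0.38 in number 3.

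The unpaired fit called 28 genes (3 higher, 25 lower) and the paired fit 1026 (335 higher, 691 lower), among them the 28; 590 of the 1026 changed at least 2-fold. The primitive endoderm list had adjusted p = 1.46e-16, or adjusted p = 0.123 with an estimated correlation; in the unpaired fit 0 members were called (15 lower when adjusted over the list alone) and the adjusted p was 0.014 with an estimated correlation. The Y-linked list had a median of -6.16 (-5.93 with Zfy1 and Usp9y at the floor), adjusted p = 4.63e-15 and adjusted p = 0.00385 with an estimated correlation. The 2-cell-like list had adjusted p = 0.0152, or adjusted p = 0.919 with an estimated correlation. The unfolded protein list had 1 member that fell, Herpud1 (6 when adjusted over the list alone), a median of -0.54 and adjusted p = 0.00545, or adjusted p = 0.597 with an estimated correlation. The mitochondrially encoded mRNAs passed in the paired fit only (median -0.29, 0 members called, also when adjusted over the list alone; adjusted p = 0.0274, or adjusted p = 0.919 with an estimated correlation; unpaired adjusted p = 0.0996). Chromosome 15 held 140 of the 691 genes that fell (20.3%), Dab2, Sqle and Itga5 among them, and had a median of -0.49. The intermediate filament Vim fell from 280 ± 52.8 to 144 ± 42.8 CPM, and Thsd7a and Ica1 rose by 5.10 and 2.64 on the log2 scale. Without unc5B MUT library 1 or 2 the unpaired fit called 7 genes, and without neo1 MUT library 1, 2 or 3 it called 6, 10 and 8. In the paired fit it gave 133, 163 and 497 without unc5B MUT library 1, 2 or 3, and 328, 331 and 428 without neo1 MUT library 1, 2 or 3. Of the 41 named genes called, 18 were called whichever library was left out. The 2-cell-like list lost its call without unc5B MUT library 1 and neo1 MUT libraries 1 and 2 (adjusted p = 0.0788, 0.236 and 0.127), and the mitochondrially encoded mRNAs without unc5B MUT libraries 1 and 2 and neo1 MUT libraries 1 and 3 (0.186, 0.247, 0.0769 and 0.127).

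The authors' deposited table of comparisons gave 900, 10 and 1124 genes at an adjusted p under 0.05 for netrin-1 WT, unc5B MUT and neo1 MUT against control. For unc5B MUT against netrin-1 WT, neo1 MUT against netrin-1 WT and neo1 MUT against unc5B MUT, the authors' deposited table gave 624, 445 and 1294. Of these calls in the authors' deposited table, 640, 6, 931, 372, 354 and 891 were also called by the paired fit with the same sign, in the same order. Across 20066 genes in both, which are not independent replicates, the log2 fold changes of the authors' deposited table and of the paired fit had Pearson correlations of 0.94 to 0.97.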

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

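The tests of primitive endoderm-like cells, of the Unc5b interaction, of female cells, of Y chromosome loss and of copy number were chosen only after the result was seen. Each list and single-gene result in this part was picked because a test of the difference between the effects of a pair of netrin-1 groups, each set against the same control, passed. The runs of neighbouring genes came from the scan and were chosen after the data were seen. Values are log2 fold changes from the paired fit. Those before and after the removal of a GC content or gene length trend are from a limma fit of log2 CPM with the same block, so they differ slightly from it.

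Primitive endoderm genes were lower in netrin-1 WT and neo1 MUT than in unc5B MUT, with list medians of 1.86 for unc5B MUT against netrin-1 WT and -1.73 for neo1 MUT against unc5B MUT (adjusted p = 0.159 and 0.123 with an estimated correlation). A trend with GC content or gene length is argued against, since the median for netrin-1 WT against control was -2.44 before such a trend was removed and -2.46 after. A smaller share of primitive endoderm-like cells in the culture may account for the pattern: the residuals of the 18 members within groups and numbers had a median pairwise correlation of 0.531, above the highest of 10000 random lists (0.399). Genes regulated together within each cell would also move together, so that test does not separate fewer cells from lower expression per cell. The Unc5b interaction that the design names cannot be told apart from a difference between transfected lines. The median of 1.86, by which this result was picked, cannot count in favour of that interaction. Chromosome 15 parts the same groups (median 0.36), and the labels do not say that a group holds several lines.

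The Y-linked list was lower in neo1 MUT, with medians of -6.24 against netrin-1 WT and -6.16 against unc5B MUT. Zfy1, Eif2s3y, Uba1y, Ddx3y and Uty had -8.77, -7.75, -7.23, -6.91 and -4.52 against netrin-1 WT and -8.43, -8.08, -6.78, -7.18 and -4.67 against unc5B MUT, where the value of Zfy1, at 1 count, depends on the prior count. Kdm5d, the list member that fell least, had -1.70 against netrin-1 WT and -1.45 against unc5B MUT. Reads moved to X-linked paralogs are argued against, since 7 X-linked partners changed by -122 CPM in sum against control (-174, -209 and 16.4 in numbers 1, 2 and 3) while the Y-linked genes lost 217 CPM. For female cells in place of a male line, the median X-linked gene changed by -0.012. It lacked the rise that 2 active X chromosomes would give, which argues against cells of that kind. Xist could not decide. It was at 3.06, 4.76 and 7.50 CPM in neo1 MUT, above the 1 CPM that would have spoken against female cells. In control, where the Y-linked genes were counted, it was higher still, at 13.2, 11.6 and 11.1 CPM. Female cells with 1 active X chromosome cannot be told apart by the values at hand. Loss of the Y chromosome may be the cause, but its test could not decide. The 17 other tested Y genes had a median against control of -2.03, with the 8 at 3 counts or fewer set at their bound. It was thus at or below that value, past the -1 that would have excluded the loss. That median fell on Rbmy, with 16 counts in control and 0 in neo1 MUT, whose bound cannot be lower. At that bound the values leave open whether the median lay below the -3 that the test called for. Genes of the 17 that kept counts in neo1 MUT, among them Gm37158 and Gm28588, also held the median up. The fitted median, which depends on the prior count, was -4.98, and -1.05 and -1.04 against netrin-1 WT and unc5B MUT. Of the 17 genes Uba1y, Zfy2 and Gm21489 fell and Mid1-ps1 rose, while Gm47283, near the end of the chromosome, was at 233 CPM in control and 228 CPM in neo1 MUT. Whether the reads of Gm47283 and Mid1-ps1 came only from the Y chromosome was not tested. These genes therefore do not count for or against loss of that chromosome.

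Runs of neighbouring genes shifted together, and Alg5 on chromosome 3 was 1 of them (-1.90 for neo1 MUT against netrin-1 WT). A GC content or gene length trend is argued against, since chromosome 3 from 5 to 55 Mb had a median of 0.90 in netrin-1 WT against control before its removal and 0.87 after. A change in copy number of the chromosome part may account for it: in the number 3 libraries the median was 0.79, against -0.17 to 0.15 in 1000 random sets of as many genes, and it was 1.01, 0.96 and 0.84 in genes of low, middle and high expression. Its bounds were set after the data were seen. The run that the scan found in numbers 1 and 2 alone (7503483 to 58557501) also had 0.79 in number 3. The number 3 libraries are of the same transfected groups, so a stable shift of expression there would repeat as well. The test does not separate such a shift from copy number. Chromosome 15 in neo1 MUT had -0.43 in the number 3 libraries, against -0.06 to 0.10, whereas in netrin-1 WT it had -0.49 and -0.46 in numbers 1 and 2 and -0.06 in number 3, so for that group copy number stays open. No explanation by netrin-1 itself was tested.

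The 2-cell-like list had a median of -1.90 for unc5B MUT against netrin-1 WT and 1.54 for neo1 MUT against unc5B MUT (-0.38 in number 3), with adjusted p = 0.538 and 0.919 with an estimated correlation. The unfolded protein list had 0.55 and -0.54 in the same comparisons (adjusted p = 0.538 and 0.597 with an estimated correlation). For unc5B MUT against netrin-1 WT the mesendoderm list had -0.46 and the mitochondrially encoded mRNAs 0.45 (adjusted p = 0.302 and 0.538 with an estimated correlation). For neo1 MUT against netrin-1 WT the naive pluripotency list had -0.19 and the imprinted list -0.46 (adjusted p = 0.682 and 0.267 with an estimated correlation). In that comparison Magea4 had -3.38 and Xlr3c -3.37. For neo1 MUT against unc5B MUT, Serpina3m had -4.33, Strada 1.23 and Firre 1.64.

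The 6 libraries of a comparison allow 10 splits, or 4 that part all 3 numbers, which is too few for a share under 0.05. Without pairing, the real split was the 1 with the most genes for netrin-1 WT, neo1 MUT, neo1 MUT against netrin-1 WT and neo1 MUT against unc5B MUT (21, 27, 16 and 28, and 0 in any other split). For unc5B MUT against control and against netrin-1 WT all 10 splits gave 0. With pairing the real split was the 1 with the most genes in each comparison: 737, 6, 1108, 414, 419 and 1026 in the order of the report, against at most 417, 0, 1, 0, 0 and 0. The 417 came from the split that exchanged the number 3 libraries of netrin-1 WT and control. For gene lists without pairing, 4, 4, 4, 4, 6 and 5 of 10 splits gave as many as the real 5, 4, 7, 5, 3 and 4, with at most 7, 7, 9, 7, 10 and 7 in another split. With pairing, 3, 2, 1, 1, 4 and 2 of 4 gave as many as the real 6, 4, 7, 6, 3 and 5, with at most 7, 7, 5, 4, 6 and 5. The 10 lists for neo1 MUT and netrin-1 WT, against the real 3, came from the split that put both number 1 libraries with neo1 MUT library 3. That split sets number 1 against number 2, and its fit has no term for the number. A list call, with or without pairing, does not by itself show a difference between groups.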

How the results depend on the processing

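Settings of the paired fit, the use of numbers 1 and 2 alone, number 3 as a covariate and counts without the chromosome parts were chosen only after the result was seen. Counts below are for netrin-1 WT, unc5B MUT and neo1 MUT against control, unc5B MUT and neo1 MUT against netrin-1 WT, and neo1 MUT against unc5B MUT, in this order, unless comparisons are named.

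The replicate block raised the count of genes in each comparison: without the block 21, 0, 27, 0, 16 and 28 genes were called, and with the replicate block 737, 6, 1108, 414, 419 and 1026, among them all called without it. It added the list calls of Nodal targets in netrin-1 WT against control and unc5B MUT against netrin-1 WT and of mitochondrially encoded mRNAs between the mutants, and it changed no other call of a list. Without the block, DESeq2 called 347, 11, 424, 182, 225 and 376 genes, and a fit of only the 2 groups compared called 0, 0, 2, 0, 1 and 2. A threshold of 0.01 gave 1, 0, 6, 0, 7 and 7, and numbers 1 and 2 alone 895, 4, 586, 431, 193 and 493. With no filter on low counts, netrin-1 WT and unc5B MUT against control and neo1 MUT against unc5B MUT gave 13, 1 and 13. At least 1 CPM in 3 libraries gave 1 for unc5B MUT against netrin-1 WT, and without the chromosome parts neo1 MUT against netrin-1 WT gave 8. Leaving out 1 library gave 1 to 6, 0 in each case, 4 to 17, 0 in each case, 8 to 9 and 6 to 20 genes. RLE size factors and limma-voom stayed within 1.5 times of every count. With the block, DESeq2 called 1737, 105, 2139, 1483, 1135 and 2180 genes, and a fit of only the 2 groups compared called 100, 1, 267, 177, 112 and 2062. With the block, a threshold of 0.01 gave 221, 3, 235, 63, 124 and 170, and numbers 1 and 2 alone 3450, 16, 2233, 2845, 627 and 2132. Limma-voom gave 1221, 901 and 1769 for netrin-1 WT against control, unc5B MUT against netrin-1 WT and neo1 MUT against unc5B MUT. No filter gave 24 and 669 for unc5B MUT against control and against netrin-1 WT, and number 3 as a covariate gave 268 for the last of these. Leaving out 1 library gave 211 to 1861, 2 to 7, 278 to 1111, 36 to 1830, 147 to 379 and 133 to 497. A stricter threshold calls fewer genes by construction; the cause of the other shifts was not tested.

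Lists called by camera numbered 5, 4, 7, 5, 3 and 4, or 6, 4, 7, 6, 3 and 5 with the block. With an estimated correlation 1, 0, 2, 1, 1 and 2 passed, and 0, 0, 1, 0, 1 and 1 with the block. For neo1 MUT against netrin-1 WT no filter gave 6 lists (5 with the block) and numbers 1 and 2 alone with the block 6. Leaving out 1 library gave 4 to 6, 2 to 7, 4 to 8, 3 to 7, 1 to 5 and 2 to 5 lists, and with the block 5 to 7, 4 to 6, 5 to 8, 4 to 8, 2 to 4 and 3 to 7. Shared calls of netrin-1 WT and unc5B MUT, netrin-1 WT and neo1 MUT, and both mutants rose from 0, 6 and 0 to 6, 147 and 5 with DESeq2 and to 5, 336 and 5 with the block. The cholesterol list in unc5B MUT against control changed direction without control library 3 (median 0.093, or 0.067 with the block); over the libraries left out its median ranged from -0.31 to 0.093, or from -0.30 to 0.067 with the block. With the block the germ-cell list in unc5B MUT against netrin-1 WT had -0.34 without netrin-1 WT library 1 (adjusted p = 0.0325; range -0.34 to 0.41). The hypoxia list in neo1 MUT against netrin-1 WT had -0.25 with numbers 1 and 2 alone (adjusted p = 0.0103). Both went against their direction with all libraries. The cause was not tested. Of the values of named genes without the block, 3643 kept their direction and side of the threshold, 361 passed only under the alternative, 261 lost the call and 0 reversed, and with the block 3615, 18, 919 and 0. For lists these counts were 1324, 53, 62 and 1, and with the block 1318, 52, 67 and 3. Summed estimated counts were lowest in the number 3 libraries (22256195 to 24736421). Their most common low value was also lower (0.498 to 0.531 counts), so the sums need not mean fewer reads. Whether this limits what these libraries show for genes of low expression was not tested.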

Other observations

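All values in this part were picked from the fixed lists or the scan of neighbouring genes, and which to name was chosen only after the result was seen.

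Single members moved in lists that as a whole did not pass the camera test in the comparisons named for them. Among ERK targets the feedback regulator Spry2 fell in both netrin-1 WT and neo1 MUT against control, from 77.3 ± 6.94 CPM to 52.9 ± 7.84 and 47.2 ± 7.02 CPM. Phlda1 fell from 26.2 ± 5.41 to 14.0 ± 1.76 and 12.7 ± 4.61 CPM, while Spry1, on chromosome 3, rose in netrin-1 WT from 16.4 ± 5.23 to 32.9 ± 11.1 CPM. The LIF target Pim1 rose from 107 ± 13.9 CPM to 160 ± 46.4 and 148 ± 17.0 CPM in the same groups. Of the de novo DNA methyltransferases, Dnmt3a fell in netrin-1 WT (352 ± 43.3 to 225 ± 13.4 CPM) and Dnmt3b in neo1 MUT (210 ± 57.2 to 137 ± 30.9 CPM); between neo1 MUT and netrin-1 WT neither Dnmt3a nor Dnmt3b passed (edgeR adjusted p = 0.222 and 0.553). In neo1 MUT against control the integrins Itga5 and Itgb5 had log2 fold changes of -0.66 ± 0.14 and -0.93 ± 0.14, while Itgav and the matrix gene Fn1 rose by 0.63 ± 0.13 and 0.65 ± 0.16. The X-linked placental gene Esx1 rose in netrin-1 WT and neo1 MUT, from 1.94 ± 1.52 to 4.76 ± 2.39 and 5.87 ± 3.29 CPM. With libraries left out 1 at a time, between 3 and 6 of the 6 ended each of these calls, except that 1 did for Spry1 and 0 for Itgb5.

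Several lists passed the camera test in none of the 6 comparisons. Their medians of the paired fit in netrin-1 WT, unc5B MUT and neo1 MUT against control were -0.22, 0.08 and -0.22 for core pluripotency, 0.14, 0.16 and 0.32 for formative and primed pluripotency, and 0.34, 0.18 and 0.12 for neuroectoderm. They were 0.04, -0.12 and -0.45 for Wnt targets, -0.12, -0.0050 and 0.10 for ERK targets, 0.0068, -0.04 and -0.17 for LIF targets and -0.14, -0.13 and -0.24 for BMP targets. Netrin receptors and related ligands had -0.0095, -0.14 and -0.08, integrins and focal adhesion 0.08, -0.03 and -0.08, and p53 targets -0.09, -0.06 and -0.06. The lowest camera adjusted p of these lists in any of the 6 comparisons was 0.137, for Wnt targets in unc5B MUT against control, or 0.0531 without pairing, for Wnt targets in neo1 MUT against control.

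Further shifts of neighbouring genes were found outside the parts described above, some as large as that of chromosome 15. In unc5B MUT against control 73 genes of chromosome 13 (21387003 to 49652785) had a median of -0.49 (-0.43 in number 3) with 0 genes called by edgeR, and the genes with over 10 CPM on chromosome 3 had 0.19 from 5 to 55 Mb and 0.20 beyond. There 40 genes of chromosome 14 (25459185 to 32179855) had -0.32 (-0.20 in number 3), also with 0 called. In neo1 MUT against control 19 genes of chromosome 13 (30540308 to 38061433) had -0.58, and 8 of them fell. Xist, the RNA that coats an inactive X chromosome, was at 3.20, 4.03 and 1.11 CPM in the netrin-1 WT libraries and at 11.8, 7.01 and 23.4 CPM in those of unc5B MUT; the paired log2 fold change between these groups was 2.18 ± 0.53 (edgeR adjusted p = 0.0632).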
